A study of Homo sapiens with 26 samples.

How the data were processed

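RNA from A549 cells, a human lung adenocarcinoma line, was measured on 26 Affymetrix HG-U133 Plus 2.0 arrays with 54675 probe sets each. Per the labels, the cells were kept without serum for 24 h and then given 5 ng/mL of TGF-beta 1. Untreated cells and cells after 0.5, 1, 4, 8, 16, 24 and 72 h gave 3 arrays each, and cells after 2 h gave 2. The labels number the arrays by experiment, so that arrays with the same number share an experiment. No untreated cells kept in culture for the same times are among the labels, so that time in culture and treatment change together.

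The authors deposited log10 values per probe set and array. Per the file headers, these are log10(max(x+50,0)+50) of trimmed means of the perfect-match minus mismatch differences, about 20 percent trimmed, made with the program readaffy at a scale constant of 1000 and quantile-normalized between arrays against 1 array as the standard. The offset of 100 inside the log understates the fold changes of weakly expressed genes. The values were converted to log2, where a difference signal of zero lies at 6.64 and the floor of the scale at 5.64. Of all values, 1.23 percent were at the floor. The deposited table also holds the authors' p-values for each time against time 0, from a model with terms for experiment and time, not adjusted for multiple tests. It further holds the authors' fold changes as ratios, and a selection of the ratios with p under 0.001 and a change of more than 2-fold. The authors' quality table, per the file headers, gives the dark factor and the number of probe sets detected per array as readaffy printed them, and the ratio of the 3' to the 5' probe set of actin. A second deposited table of the log10 values differed from the first by at most 5.00e-10. Detection calls per probe set and the scanned intensities were not used here. The number of arrays limits the precision of every value.

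Gene symbols came from the deposited annotation and were brought up to date through the Entrez gene number where the gene table held it, for 38088 of 39321 probe sets with 1 gene. The 62 control probe sets, 1208 probe sets with several genes and 14084 without a symbol were left out of the gene tests. Of the 19539 genes, 10314 had more than 1 probe set, and each gene took its probe set with the highest mean over all arrays, with a preference for sets not marked as cross-hybridizing. Genes were tested if the value lay above the array's median on at least 2 arrays, which kept 14771 and removed 4768. The median of all probe sets was 7.96 on every array.

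Group means were compared with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with lmFit and eBayes with an intensity trend, on all 26 arrays in 9 groups with 17 residual degrees of freedom. Each time was compared with untreated cells, 24 h with 1 h, and 72 h with 24 h. The moderated tests were two-sided and adjusted over genes by the Benjamini-Hochberg method at a threshold of 0.05. A moderated F test asked for any change over the 8 times. The experiment number was not a term of the model but was tried as a block, as the authors' own model has it. Standard errors are the moderated ones of limma. Per the labels the arrays of a group come from separate repeats of the experiment. The p-values measure only the spread between arrays within groups, pooled over all 9 groups. A gene's standard error is thus the same at every time with 3 arrays, even where its spread differed between groups. For SMAD7, for instance, the SD was 1.185 at 0.5 h and 0.056 at 72 h. All times share the same 3 untreated arrays, so the comparisons with them are not independent of one another.

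For 27 lists of genes, camera from limma was run with the preset correlation of 0.01 between genes, adjusted over the lists of a comparison, with at least 5 measured genes per list. Camera with an estimated correlation and fry, a rotation test of a list on its own, were the alternatives. The lists, comparisons, tests, alternatives and the rule for named genes were set before the data were examined. That rule took, at 1, 4, 24 and 72 h, the 10 largest rises and 10 largest falls among genes past the threshold whose treated arrays all lay beyond all untreated arrays. At 0.5, 2, 8 and 16 h it took up to 3 each way, and for the differences between times up to 5 each way. It added the members of each described list with the largest changes, and SMAD7, SKIL, CDH1, CDH2, VIM, FN1, SNAI1, SNAI2 and ZEB1 whatever their result. Some genes that meet this rule are not reported here.

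Alternatives covered the experiment block, other filters, a second quantile normalization, centring on the median, a further offset of 50, eBayes without trend or robust, the mean of a gene's probe sets, all probe sets, a fit on only the groups compared, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each array in turn. An exchanged numbering of untreated arrays 2 and 3 in the block, and a fit without 3 arrays marked with r in the authors' table, were added after seeing the data. Families of gene symbols were also tested after seeing the data. The procedure was tested on simulated data made from these values. With 50 genes changed at each size among 14771, the 24 h comparison called 34, 72, 98 and 100 percent at log2 changes of 0.5, 1, 2 and 3. It made 9 false calls, 5.59 percent of its calls, and called 0 of 100 random lists. The simulated genes varied independently of one another and with the same spread in every group. The simulation therefore does not show how often lists of genes that vary together are called falsely. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.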

Results

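Gene expression was measured in A549 cells, a human lung adenocarcinoma line with features of alveolar epithelium, over 72 h with TGF-beta 1, a cytokine known to drive epithelial cells towards a mesenchymal state. The 26 arrays form 9 groups of 3, except the 2 h group of 2 arrays. Between 28834 and 32875 of the 54675 probe sets were detected per array (median 31262), 52.7 to 60.1 percent. The lowest number was that of 24 h replicate 1, and the 24 h group had the lowest mean, 30354 ± 1585 (SD, n = 3). The ratio of the 3' to the 5' probe set of actin, a sign of RNA quality, ranged from 0.975 to 1.16. Its group mean was 1.10 ± 0.0298 (SD, n = 3) in untreated cells and 1.00 ± 0.0264 (SD, n = 3) at 24 h. Levels are on a log2 scale on which a signal of zero lies at 6.64 and the floor at 5.64. Below, changes are log2 changes ± limma's standard error with n = 3 arrays per group (n = 2 at 2 h), and folds of weakly expressed genes are understated by the offset in the deposited values.

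The number of changed genes grew from 0.5 to 72 h, as the plot of counts by time shows. Of 14771 genes, 7040 (47.7 percent) varied over the time course by the F test of limma, and without experiment 1 or experiment 2 the number was 3769 or 3493. Without experiment 3 the number was 6640, and of these fits only this one keeps at least 2 arrays in every group. Arrays of the same group correlated across genes at a median r of 0.979 (0.959 to 0.990, 25 pairs), and arrays of different groups at a median r of 0.949 (0.873 to 0.992, 300 pairs), so the ranges overlap. The first principal component held 53.8 percent of the variance and the second 10.8 percent. The actin 3'/5' signal ratio, a sign of RNA quality, had a mean of 1.10 in untreated cells, 1.11 at 0.5 h and at 2 h, and lower means at the other times. These were 1.03 at 1 h, 1.04 at 4 h, 1.03 at 8 h, 1.02 at 16 h, 1.00 at 24 h and 1.01 at 72 h, and no test was run on them.

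**Figure D1:**
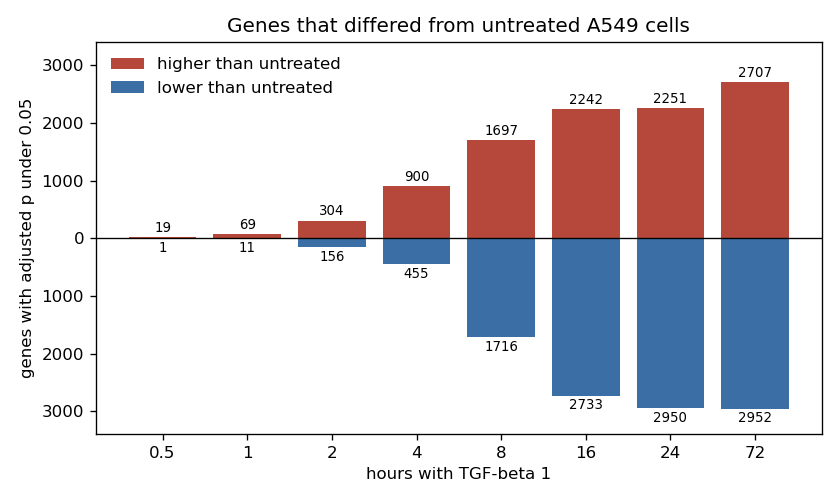
Number of genes with adjusted p under 0.05 (vertical axis) at each time with TGF-beta 1 (horizontal axis, hours), with genes higher than in untreated cells above 0 and lower ones below. The bars grow from 19 higher and 1 lower at 0.5 h to 2707 higher and 2952 lower at 72 h.

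The earliest time asks which genes respond first. After 0.5 h, JUNB, a subunit of the AP-1 transcription factor, rose 6.85-fold (2.78 ± 0.22, adjusted p 3.65e-07), and JUN, another AP-1 subunit, rose 5.70-fold (2.51 ± 0.23, adjusted p 1.67e-06). SKIL, a repressor of SMAD signalling, rose 5.10-fold (2.35 ± 0.30, adjusted p 0.000171), and SMAD7, an inhibitory SMAD, rose by 1.90 ± 0.38 (adjusted p 0.0399). The only gene lower was LOC732229 (-0.85 ± 0.16, adjusted p 0.0313). In all, 20 genes passed, 19 higher and 1 lower. Among the TGF-beta feedback genes and direct targets, 7 of 28 rose and 0 fell (11 and 0 adjusted over the list alone), with JUNB and SKIL at the top (camera adjusted p 7.24e-21, 0.000627 with an estimated correlation). Among the immediate-early regulators, 7 of 28 rose and 0 fell (12 and 1 adjusted over the list alone), with JUNB and JUN at the top (adjusted p 9.41e-21, 0.000807 with an estimated correlation). No G1/S, G2/M or cholesterol gene passed alone, yet these lists lay lower than other genes, at medians of -0.37, -0.35 and -0.27 (adjusted p 1.14e-08, 0.00182 and 4.06e-06). With an estimated correlation those became adjusted p = 0.516, adjusted p = 0.701 and adjusted p = 0.516. Without untreated replicate 1 they were 0.583, 0.587 and 0.181. In that fit the G2/M list turned to the higher side. The G2/M list also lost its call without untreated replicate 3 (0.159), and the G1/S and G2/M lists without 0.5 h replicate 3 (0.107 each). Here too the G2/M list turned to the higher side. The WNT and Notch list was higher (adjusted p 0.0158), with adjusted p = 0.274 with an estimated correlation, and 0.0588, 0.192 and 0.534 without untreated replicates 1 and 2 and 0.5 h replicate 3. SMAD7 missed the threshold with the experiment as a block (0.0509, but 0.0366 with the numbers of untreated replicates 2 and 3 exchanged, a fit added after the data were seen), without an intensity trend (0.0781), with robust eBayes (0.118), with only these groups in the fit (1.00), and with 1 array fewer. This was so without untreated replicates 1, 2 and 3 (0.0533, 0.228 and 0.230) and 0.5 h replicates 2 and 3 (0.236 and 0.424). LOC732229 missed it without the same arrays (0.0533, 0.0532, 0.271, 0.222 and 0.142) and with only these groups in the fit (0.987). The count was 13 without untreated replicate 2 or 3, 42 without 0.5 h replicate 1, and 2 with only these groups in the fit, where JUNB had an adjusted p of 0.0854 and JUN of 0.142.

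After 1 h, JUNB rose 9.30-fold (3.22 ± 0.22, adjusted p 2.02e-08) and JUN 7.48-fold (2.90 ± 0.23, adjusted p 1.60e-07). The Notch targets HES1 (2.55 ± 0.48) and HEY1 (2.41 ± 0.44) and the Notch modifier LFNG (2.15 ± 0.35) rose, as did SMAD7 (2.52 ± 0.38), SKIL (2.10 ± 0.30), ID3, an inhibitor of DNA binding (2.24 ± 0.32), and GADD45B, a stress response gene (2.05 ± 0.27). CXCL3, a chemokine, fell by 2.44 ± 0.39, PLK2, a stress-response kinase, fell by 2.12 ± 0.34, and CEBPD, a C/EBP transcription factor, fell by 1.89 ± 0.34. Smaller falls were seen for TENT5A (-1.54 ± 0.30), LOC732229 (-1.04 ± 0.16), the transcription factor MYC (-1.01 ± 0.18), the phosphatase DUSP5 (-0.84 ± 0.15), CD300LB (-0.80 ± 0.16) and NABP1 (-0.70 ± 0.12). CPS1-IT1 was lower by -2.53 ± 0.48, with a mean of 6.38 at 1 h, under the level of zero signal. In all, 80 genes passed, 69 higher and 11 lower.

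Of the lists at 1 h, the TGF-beta targets had 10 of 28 higher and 0 lower (14 and 0 adjusted over the list alone), led by JUNB and SMAD7 (camera adjusted p 4.25e-28, 0.000102 with an estimated correlation). The immediate-early regulators had 10 of 28 higher and 2 lower (12 and 2 adjusted over the list alone), led by JUNB and JUN (adjusted p 1.91e-13, 0.00756 with an estimated correlation). The WNT and Notch list had 3 of 32 higher and 0 lower (3 and 0 adjusted over the list alone), HES1, HEY1 and LFNG (adjusted p 9.73e-05, 0.0217 with an estimated correlation). Transcription factors linked to epithelial-mesenchymal transition (EMT factors) had 1 of 15 higher, SOX4 (0.53 ± 0.11), and SNAI2 at 0.75 ± 0.34, with a camera adjusted p of 0.0129 (0.0368 with an estimated correlation, 0.137 without untreated replicate 2). The G1/S list (adjusted p 0.00113) and the cholesterol list (adjusted p 0.0111) were lower with no member passing. With an estimated correlation both gave adjusted p = 0.785. The G1/S list lost its call without untreated replicate 1 (0.436, on the higher side) or 1 h replicate 3 (0.243), and the cholesterol list without untreated replicate 1 (0.600) or 1 h replicates 1 and 2 (0.0564 and 0.175). The G2/M list, at 0.131, passed on the lower side without untreated replicate 2 (3.32e-08) or 1 h replicates 1 and 2 (0.00823 and 0.00334). Without 1 h replicate 2, HES1 (0.0871), CPS1-IT1 (0.0940), TENT5A (0.101), MYC (0.0505) and CD300LB (0.0918) missed the threshold, and without 1 h replicate 1, HES1 (0.0642), CPS1-IT1 (0.0642) and TENT5A (0.0534). Without untreated replicate 1, HEY1 (0.0521) and SOX4 (0.0529) did. Without untreated replicate 2, TENT5A (0.0814), CD300LB (0.0947) and SOX4 (0.0578) did. Without untreated replicate 3, CPS1-IT1 (0.0923), TENT5A (0.0620), DUSP5 (0.0582) and SOX4 (0.117) did, and without 1 h replicate 3, SOX4 (0.125). As the mean of their probe sets, HES1 (1.45, adjusted p 0.0596), TENT5A (-0.88, 0.179), MYC (-0.21, 0.962) and CD300LB (-0.21, 0.945) also missed it. The count was 51 without untreated replicate 3, 44 without 1 h replicate 2, and 24 with only these groups in the fit. There SMAD7 (0.0550), SKIL (0.108), MYC (0.108), GADD45B (0.132), DUSP5 (0.161), NABP1 (0.179), LOC732229 (0.186), CPS1-IT1 (0.242), CD300LB (0.269), PLK2 (0.309), SOX4 (0.330), HES1 (0.425) and TENT5A (0.0743) missed the threshold. SOX4 also missed it without an intensity trend (0.0650).

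After 2 h, with 2 treated arrays, IL11, a cytokine of the IL-6 family, rose 9.96-fold (3.32 ± 0.51, adjusted p 0.000668). ID4, an inhibitor of DNA binding, rose by 3.83 ± 0.99 (adjusted p 0.0335). PDK4, a pyruvate dehydrogenase kinase, fell by 3.24 ± 0.42, and the chemokines CCL20 and CXCL3 fell by 3.24 ± 0.79 and 2.64 ± 0.43. In all, 460 genes passed, 304 higher and 156 lower. The TGF-beta targets had 13 of 28 higher and 0 lower (16 and 0 adjusted over the list alone), such as JUNB (3.26 ± 0.25), with a camera adjusted p of 3.12e-21 (0.000566 with an estimated correlation). The WNT and Notch list had 4 of 32 higher and 0 lower (9 and 1 adjusted over the list alone), led by LFNG (3.02 ± 0.39) and HEY1 (2.34 ± 0.49), at an adjusted p of 6.36e-05 (0.0239 with an estimated correlation). The immediate-early regulators had 8 of 28 higher and 1 lower (9 and 3 adjusted over the list alone), led by JUNB and JUN (3.02 ± 0.26), at 0.000382, and adjusted p = 0.256 with an estimated correlation. The TGF-beta superfamily list had 2 of 39 higher and 0 lower (6 and 0 adjusted over the list alone), FSTL3, a follistatin-like antagonist (1.69 ± 0.23), and SMAD1 (0.50 ± 0.12), at 0.0413, and adjusted p = 0.256 with an estimated correlation. The cholesterol list was lower at 0.00673, and adjusted p = 0.567 with an estimated correlation. The superfamily list lost its call without untreated replicate 3 (0.0890) or 2 h replicate 1 (0.462), and the cholesterol list without untreated replicate 1 (0.219) or 2 h replicate 2 (0.0513). The G1/S and G2/M lists, at 0.823 and 0.653, passed on the higher side without untreated replicate 1 (0.00573 and 0.00991) and on the lower side without untreated replicate 2 (0.00787 and 0.0171). Their direction at 2 h thus changed with the untreated array left out. Without 2 h replicate 1, ID4 (0.384), CCL20 (0.318), CXCL3 (0.0678), HEY1 (0.128), SMAD1 (0.188), SMAD7 (0.115) and SKIL (0.0652) missed the threshold, and without 2 h replicate 2, ID4 (0.115), CCL20 (0.0878), HEY1 (0.0751) and SMAD1 (0.189). ID4 and CCL20 also missed it without untreated replicate 1 (0.0929 and 0.0514) and replicate 3 (0.0977 and 0.0874), SMAD1 without untreated replicate 2 (0.115) and as the mean of its probe sets (0.34, 0.244), and ID4 with robust eBayes (0.0629). The count was 68 and 146 without 2 h replicates 1 and 2, where the lone array was assumed to vary like the other groups.

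After 4 h, ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 22.3-fold (4.48 ± 0.51, adjusted p 1.12e-05), and the transcription factor MAF rose by 4.17 ± 0.57 (adjusted p 4.80e-05). MYOCD, a coactivator of smooth muscle genes (3.63 ± 0.58), PPP1R14C, a phosphatase inhibitor (3.42 ± 0.39), JUN (3.37 ± 0.23), PIK3AP1 (3.12 ± 0.44), collagen gene COL1A1 (3.12 ± 0.42), JUNB (3.08 ± 0.22) and TNS4, a tensin (2.91 ± 0.39) also rose. IGFBP1, which binds insulin-like growth factors, fell by 3.51 ± 0.52, and INHBB, the activin beta B subunit, fell by 3.16 ± 0.36. Falls were also seen for the receptor KIT (-2.86 ± 0.49), the epithelial transcription factor EHF (-2.76 ± 0.38), PDK4 (-2.66 ± 0.37), the transcription factor SOX2 (-2.59 ± 0.58), CCL20 (-2.56 ± 0.70), fibrinogen gene FGA (-2.44 ± 0.45), the sialyltransferase ST8SIA4 (-2.26 ± 0.38) and CEBPD (-2.13 ± 0.34). In all, 1355 genes passed, 900 higher and 455 lower. CCL20 missed the threshold without untreated replicates 1 and 3 (0.0529 and 0.0983) or 4 h replicate 3 (0.107). The count was 869 and 836 without 4 h replicates 1 and 2, and 781 with only these groups in the fit.

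Of the lists at 4 h, 12 passed and only the TGF-beta targets kept the call with an estimated correlation. They had 17 of 28 higher and 1 lower (24 and 1 adjusted over the list alone), such as JUNB, at an adjusted p of 7.23e-19 (0.00112 with an estimated correlation). Matrix proteases, their inhibitors and collagen-modifying enzymes (matrix remodelling) had 10 of 49 higher and 0 lower (13 and 0 adjusted over the list alone), such as P4HA3 (1.97 ± 0.34), at 0.000371, and adjusted p = 0.0501 with an estimated correlation. The immediate-early regulators had 10 higher and 1 lower of 28 (11 and 2 adjusted over the list alone) and the WNT and Notch list 8 and 0 of 32 (8 and 0 adjusted over the list alone), at 1.36e-05 and 0.00498, each with adjusted p = 0.107 with an estimated correlation. Structural matrix genes had 7 of 42 higher and 0 lower (8 and 0 adjusted over the list alone), led by COL1A1 and THBS1 (2.33 ± 0.35), at 0.00700, and adjusted p = 0.378 with an estimated correlation (0.0615 without 4 h replicate 1). The TGF-beta superfamily had 6 of 39 higher and 3 lower (10 and 4 adjusted over the list alone), led by INHBB and FSTL3 (1.66 ± 0.20), at 0.0126, and adjusted p = 0.119 with an estimated correlation. Mesenchymal markers had 4 of 24 higher and 0 lower (4 and 0 adjusted over the list alone), and actin and contractile genes 7 of 38 and 0 (8 and 0 adjusted over the list alone). Both stood at 0.0316, with adjusted p = 0.402 and adjusted p = 0.572 with an estimated correlation. Hypoxia and glycolysis genes had 7 of 26 higher and 2 lower (8 and 2 adjusted over the list alone), led by ANGPTL4 and PFKFB3 (1.83 ± 0.34), at 0.0179, and adjusted p = 0.400 with an estimated correlation. The NRF2 and glutathione list had 1 of 27 higher, HMOX1, heme oxygenase (2.58 ± 0.42), and 6 lower, such as ABCC2 (-1.37 ± 0.35) and OSGIN1 (-1.25 ± 0.25), or 2 and 8 adjusted over the list alone. It stood at 0.0112, with adjusted p = 0.378 with an estimated correlation. The G1/S list (2 lower and 1 higher of 39, led by CDK6 at -1.02 ± 0.18) and the G2/M list (1 lower of 39, ECT2 at -1.05 ± 0.28) were lower at 1.46e-05 and 0.0112, with adjusted p = 0.528 and adjusted p = 0.663 with an estimated correlation. Adjusted over the list alone, each had 1 lower. Without untreated replicate 1, the G1/S (0.122) and G2/M lists (0.631) lost their calls. Without untreated replicate 2, mesenchymal markers (0.0589), actin genes (0.171), NRF2 genes (0.0592) and hypoxia genes (0.0589) did. Without untreated replicate 3, mesenchymal markers (0.0686), actin genes (0.0799), G2/M genes (0.0686) and hypoxia genes (0.0917) did. Without 4 h replicate 1, mesenchymal markers (0.172) and actin genes (0.178) did, without 4 h replicate 2, actin genes (0.0559), and without 4 h replicate 3, G2/M genes (0.607). ABCC2 missed the threshold without untreated replicate 2 (0.0734) and 4 h replicates 1 and 2 (0.130 and 0.0527), and ECT2 without untreated replicates 1 and 3 (0.123 and 0.0670) and 4 h replicates 2 and 3 (0.0750 and 0.0645). Integrin genes, at 0.0520 with 3 of 16 higher and 0 lower, passed with the experiment as a block (0.0325) and without 4 h replicate 3 (0.00884). Cholesterol genes, at 0.130, passed on the lower side without untreated replicate 3 (0.00624).

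After 8 h, MAF rose 34.9-fold (5.12 ± 0.57, adjusted p 1.02e-06), ANGPTL4 34.8-fold (5.12 ± 0.51, adjusted p 3.03e-07) and MYOCD 24.1-fold (4.59 ± 0.58, adjusted p 4.71e-06). CCL20 fell by 4.89 ± 0.70, to a mean of 6.50 under the level of zero signal, INHBB fell by 4.28 ± 0.36 and KIT fell by 3.86 ± 0.49. The G1/S and DNA replication list had 27 of 39 lower and 1 higher (31 and 2 adjusted over the list alone), led by the helicase subunits MCM2 (-1.96 ± 0.40) and MCM6 (-1.76 ± 0.26), at 1.00e-10, and adjusted p = 0.200 with an estimated correlation. The TGF-beta targets had 23 of 28 higher and 1 lower (24 and 1 adjusted over the list alone), at 9.76e-16 (0.00175 with an estimated correlation). Matrix remodelling genes had 22 of 49 higher and 0 lower (23 and 0 adjusted over the list alone), such as the protease MMP10 (2.68 ± 0.40), at 3.19e-08 (0.00175 with an estimated correlation). Integrins had 8 of 16 higher and 0 lower (10 and 0 adjusted over the list alone), led by ITGA2 (2.19 ± 0.22) and ITGB4 (1.55 ± 0.20), at 7.63e-05 (0.0249 with an estimated correlation). Another 12 lists passed, 10 higher and 2 lower, and none of these kept the call with an estimated correlation. Of these, structural matrix genes had 19 of 42 higher and 1 lower, at 8.34e-07 and adjusted p = 0.0625 with an estimated correlation, and NRF2 genes 11 of 27 lower and 1 higher, at 2.83e-06 and adjusted p = 0.0512 with an estimated correlation. The G2/M list had 1 of 39 lower, ECT2 (-1.20 ± 0.28), at 0.00888 and adjusted p = 0.718 with an estimated correlation, and lost its call without untreated replicate 1 (0.430) or 8 h replicate 3 (0.338). Hypoxia genes (0.0484) lost theirs with the experiment as a block (0.0535) and without untreated replicates 2 and 3 (0.0955 and 0.154) or 8 h replicates 1 and 3 (0.0523 and 0.103). The p53 targets (0.0347) did so without untreated replicate 3 (0.101) or 8 h replicate 3 (0.175). Cholesterol genes, at 0.216, passed on the lower side without untreated replicate 3 (0.0190) or 8 h replicate 3 (0.0315). With an estimated correlation the hypoxia and p53 lists both gave adjusted p = 0.459. In all, 3413 genes passed, 1697 higher and 1716 lower, or 2225 with only these groups in the fit.

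After 16 h, IL11 rose 69.2-fold (6.11 ± 0.46, adjusted p 1.37e-09), IGFL1, an IGF-like family gene, 59.7-fold (5.90 ± 0.44, adjusted p 1.17e-09), and IGFBP5, which binds insulin-like growth factors, 58.2-fold (5.86 ± 0.58, adjusted p 5.58e-08). CCL20 lay at the floor on all 3 arrays, so its change of -5.74 ± 0.70 is a lower bound of the fall, TM4SF20 fell by 5.08 ± 0.45 and INHBB fell by 4.61 ± 0.36. The cholesterol list had 16 of 24 lower and 0 higher (20 and 0 adjusted over the list alone), such as ACAT2 (-1.89 ± 0.30), at 2.26e-06, and adjusted p = 0.295 with an estimated correlation. NRF2 and glutathione genes had 23 of 27 lower and 0 higher (23 and 0 adjusted over the list alone), led by the exporter ABCC2 (-3.08 ± 0.35) and the reductase AKR1C2 (-2.95 ± 0.28), at 2.33e-12 (0.00544 with an estimated correlation). The G1/S list had 33 of 39 lower and 3 higher (33 and 3 adjusted over the list alone), led by MCM2 (-2.53 ± 0.40) and GINS2 (-2.47 ± 0.37), at 4.54e-10, and adjusted p = 0.227 with an estimated correlation. EMT factors had 8 of 15 higher and 2 lower (10 and 2 adjusted over the list alone), led by SNAI2 (3.02 ± 0.34) and HMGA2 (2.25 ± 0.28), at 0.00168 (0.0149 with an estimated correlation). In all, 4975 genes passed, 2242 higher and 2733 lower, and 16 lists, of which 8 kept the call with an estimated correlation. The G2/M list (3 of 39 lower, at 0.0137, and adjusted p = 0.756 with an estimated correlation) lost its call without untreated replicates 1 and 3 (0.361 and 0.0562) or 16 h replicate 3 (0.204), and the p53 list (0.0120, adjusted p = 0.315 with an estimated correlation) without 16 h replicate 3 (0.0939).

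After 24 h, IGFL1 rose 125.0-fold (6.97 ± 0.44, adjusted p 7.32e-11) and IL11 100.1-fold (6.64 ± 0.46, adjusted p 2.37e-10). IGFBP5 (6.48 ± 0.58), IGFBP7 (6.13 ± 0.52), MAF (5.62 ± 0.57), collagen genes COL5A1 (5.45 ± 0.50) and COL4A1 (5.23 ± 0.43), CORO2B, an actin-binding coronin (5.29 ± 0.25) and ANGPTL4 (5.28 ± 0.51) also rose. Falls were led by CCL20, at the floor on all 3 arrays (-5.74 ± 0.70 as a lower bound), the tetraspanin-like TM4SF20 (-5.66 ± 0.45) and the amino acid transporter SLC7A2 (-5.03 ± 0.32). EHF (-4.73 ± 0.38), INHBB (-4.64 ± 0.36), AGR2, a disulfide isomerase of secretory epithelia (-4.64 ± 0.30), the aldehyde dehydrogenase ALDH3A1 (-4.62 ± 0.26), TSPAN8 (-4.62 ± 0.38), DDC, which makes dopamine and serotonin (-4.55 ± 0.26), and fibrinogen gene FGB (-4.46 ± 0.48) followed. In all, 5201 genes passed, 2251 higher and 2950 lower, of which 1651 changed at least 2-fold. The count was 3223 without the 3 arrays marked with r, which leaves 1 array at 24 h.

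Mesenchymal markers at 24 h had 14 of 24 higher and 0 lower (16 and 0 adjusted over the list alone), such as COL1A1 (4.14 ± 0.42), at an adjusted p of 1.10e-08 (0.0116 with an estimated correlation). EMT factors had 10 of 15 higher and 2 lower (11 and 2 adjusted over the list alone), led by SNAI2 (3.61 ± 0.34) and HMGA2 (2.79 ± 0.28), at 0.000704 (0.00778 with an estimated correlation). The TGF-beta targets had 22 of 28 higher and 1 lower (22 and 1 adjusted over the list alone), such as LTBP2 (3.28 ± 0.29), at 9.25e-14 (0.00223 with an estimated correlation). Matrix remodelling genes had 29 of 49 higher and 2 lower (29 and 2 adjusted over the list alone), such as the protease ADAM19 (4.16 ± 0.27), at 4.09e-10 (0.00108 with an estimated correlation). Structural matrix genes had 25 of 42 higher and 4 lower (25 and 4 adjusted over the list alone), such as COL5A1, at 4.05e-08 (0.0353 with an estimated correlation). Integrins had 9 of 16 higher and 1 lower (9 and 1 adjusted over the list alone), led by ITGA11 (3.61 ± 0.24) and ITGA2 (2.78 ± 0.22), at 4.97e-05 (0.0116 with an estimated correlation). The TGF-beta superfamily list, led by INHBB and the activin antagonist FST (3.45 ± 0.62), had 17 of 39 higher and 8 lower (17 and 9 adjusted over the list alone), at 0.00455. Growth factor genes, led by IGFBP5 and IGFBP7, had 19 of 35 higher and 7 lower (20 and 7 adjusted over the list alone), at 0.00106. Both stood at 0.0494 with an estimated correlation. Actin and contractile genes had 23 of 38 higher and 2 lower (24 and 4 adjusted over the list alone), led by TAGLN, transgelin (4.63 ± 0.42), and LMCD1 (3.67 ± 0.28), at 4.14e-07, and adjusted p = 0.0702 with an estimated correlation. Epithelial junction and keratin genes went both ways, with 9 of 35 higher and 14 lower (9 and 15 adjusted over the list alone), CDH1 (-3.34 ± 0.17) and the transcription factor ELF3 (-3.09 ± 0.35) leading, at 0.194.

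At 24 h, the G2/M and mitosis list had 34 of 39 lower and 0 higher (39 and 0 adjusted over the list alone, median -1.91), led by the spindle gene ASPM (-2.75 ± 0.53) and HMMR (-2.35 ± 0.71), at 2.58e-07, and adjusted p = 0.464 with an estimated correlation. HMMR missed the threshold without untreated replicate 1 (0.0828) or 24 h replicate 1 (0.0509). The G1/S list had 29 of 39 lower and 2 higher (31 and 3 adjusted over the list alone), led by thymidine kinase TK1 (-2.12 ± 0.56) and E2F2 (-1.89 ± 0.36), at 4.97e-05, and adjusted p = 0.452 with an estimated correlation. Of the cyclin-dependent kinase inhibitors, 2 of 7 rose and 3 fell (3 and 3 adjusted over the list alone), such as CDKN3 (-2.36 ± 0.62) and CDKN2C (-1.42 ± 0.37), at 0.903. The p53 targets had 9 of 23 higher and 1 lower (9 and 1 adjusted over the list alone), led by TP53I3 (2.30 ± 0.16) and DDB2 (2.24 ± 0.29), at 0.00580, and adjusted p = 0.296 with an estimated correlation. NRF2 and glutathione genes had 25 of 27 lower and 0 higher (25 and 0 adjusted over the list alone, median -0.92), led by ALDH3A1 and AKR1C2 (-3.21 ± 0.28), at 2.03e-15 (0.00223 with an estimated correlation). Cholesterol genes had 10 of 24 lower and 0 higher (10 and 0 adjusted over the list alone), such as TM7SF2 (-1.36 ± 0.25), at 0.0139, with adjusted p = 0.532 with an estimated correlation and 0.106 and 0.332 without untreated replicate 1 and 24 h replicate 3. Interferon-stimulated genes had 9 of 25 lower and 1 higher (10 and 1 adjusted over the list alone), led by IFIT1 (-2.04 ± 0.39) and IFIT2 (-1.49 ± 0.28), at 0.0289, with adjusted p = 0.452 with an estimated correlation and 0.0805 and 0.0517 without untreated replicate 3 and 24 h replicate 1.

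Other lists at 24 h moved less evenly. Immediate-early regulators had 12 of 28 higher and 5 lower (12 and 5 adjusted over the list alone), led by JUN (3.56 ± 0.23) and EGR2 (3.45 ± 0.41), at 0.00455, and adjusted p = 0.230 with an estimated correlation. WNT and Notch genes had 14 of 32 higher and 5 lower (16 and 6 adjusted over the list alone), led by AXIN2 (-2.34 ± 0.33) and MAML2 (2.24 ± 0.23), at 0.0223, and adjusted p = 0.150 with an estimated correlation. Alveolar and airway lineage genes had 2 of 20 higher and 6 lower (2 and 6 adjusted over the list alone), led by CEBPD (-3.09 ± 0.34) and the water channel AQP3 (-2.98 ± 0.32), at 0.0763, and 0.0424 without untreated replicate 1. NF-kappaB targets and cytokines had 6 of 29 higher and 9 lower (6 and 9 adjusted over the list alone), led by IL11 and CCL20, at 0.692, with a median of 0.08 and a mean of -0.28. Hypoxia and glycolysis genes had 10 of 26 higher and 8 lower (10 and 9 adjusted over the list alone), led by ANGPTL4 and CA9 (-2.17 ± 0.24), at 0.186. Unfolded protein genes had 3 of 26 higher and 4 lower (3 and 4 adjusted over the list alone), led by XBP1 (-1.55 ± 0.21) and DNAJB9 (-0.84 ± 0.24), at 0.848. Reference genes had 2 of 15 higher and 6 lower (2 and 6 adjusted over the list alone), such as HPRT1 (-0.53 ± 0.14), at 0.428, and HPRT1 gave -0.27 (adjusted p 0.0936) as the mean of its probe sets. Leukocyte markers had 2 of 9 higher and 2 lower (3 and 2 adjusted over the list alone), led by LAPTM5 (1.00 ± 0.14) and CSF1R (0.70 ± 0.23), at 0.370. CSF1R missed the threshold without untreated replicate 3 (0.0604) or 24 h replicates 1 and 2 (0.0536 and 0.0890). Endothelial markers had 1 of 5 higher, ESAM (2.19 ± 0.25), and 1 lower, TEK (-0.70 ± 0.23), at 0.729, with 1 and 1 adjusted over the list alone. TEK missed the threshold without untreated replicate 2 (0.154) or 24 h replicate 3 (0.152), gave 0.04 (adjusted p 0.903) as the mean of its probe sets, and had another probe set that rose (0.78). Fibroblast markers had 0 of 8 past the threshold by limma, over all genes or adjusted over the list alone, with a median of -0.18, at 0.672.

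After 72 h, IGFL1 rose 166.0-fold (7.37 ± 0.44, adjusted p 1.55e-11), and MAF 96.6-fold (6.59 ± 0.57, adjusted p 4.89e-09). IGFBP5 (6.43 ± 0.58), IGFBP7 (6.41 ± 0.52), IL11 (6.21 ± 0.46), the proteoglycan gene SPOCK1 (6.14 ± 0.33), COL5A1 (5.92 ± 0.50), IGFL2 (5.83 ± 0.35), the cornified envelope gene LCE3D (5.47 ± 0.30) and the potassium channel gene KCNMA1 (5.33 ± 0.29) also rose. The airway mucin gene MUC5B fell by 7.14 ± 0.34 to a mean of 5.97, CCL20 to the floor on all 3 arrays (-5.74 ± 0.70), and the cytochrome gene CYP4F11 fell by 5.51 ± 0.23 to a mean of 5.68, all under the level of zero signal. ALDH3A1 (-6.63 ± 0.26), CP, ceruloplasmin (-6.35 ± 0.30), TM4SF20 (-6.04 ± 0.45), the lipocalin LCN2 (-5.98 ± 0.44), the protease inhibitor SLPI (-5.25 ± 0.29), the claudin CLDN2 (-5.16 ± 0.53) and the protease MMP7 (-5.11 ± 0.22) also fell. In all, 5659 genes passed, 2707 higher and 2952 lower, of which 1690 changed at least 2-fold.

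Of the lists at 72 h, 19 passed and 6 kept the call with an estimated correlation. NRF2 and glutathione genes had 24 of 27 lower and 1 higher (24 and 1 adjusted over the list alone, median -1.11), led by ALDH3A1 and the glutathione peroxidase GPX2 (-5.10 ± 0.22), at 1.70e-15 (0.00486 with an estimated correlation). Mesenchymal markers had 16 of 24 higher and 2 lower (16 and 2 adjusted over the list alone), such as COL1A1 (4.42 ± 0.42), at 2.88e-07 (0.0259 with an estimated correlation). EMT factors had 10 of 15 higher and 3 lower (10 and 3 adjusted over the list alone), led by SNAI2 (4.43 ± 0.34) and HMGA2 (2.98 ± 0.28), at 0.00179 (0.0111 with an estimated correlation). The other 3 were the TGF-beta targets (22 of 28 higher), matrix remodelling genes (24 of 49 higher and 4 lower) and the TGF-beta superfamily (17 of 39 higher and 6 lower), at 0.00678, 0.00750 and 0.0486 with an estimated correlation. Epithelial genes had 8 of 35 higher and 17 lower (9 and 18 adjusted over the list alone), led by CLDN2 and CDH1 (-4.26 ± 0.17), at 0.0242, with adjusted p = 0.253 with an estimated correlation and 0.0510 without untreated replicate 3. Interferon-stimulated genes had 13 of 25 lower and 2 higher (14 and 2 adjusted over the list alone), led by IFIT1 (-2.08 ± 0.39) and PSMB9 (-1.92 ± 0.33), at 0.00253, and adjusted p = 0.202 with an estimated correlation. Alveolar and airway genes had 7 of 20 lower and 1 higher (7 and 1 adjusted over the list alone), led by MUC5B and MUC5AC (-4.25 ± 0.36), at 0.0350, with adjusted p = 0.131 with an estimated correlation, 0.0550 with the experiment as a block and 0.0501 without untreated replicate 3. The G1/S list had 17 of 39 lower and 2 higher (19 and 3 adjusted over the list alone), at 0.00298, with adjusted p = 0.563 with an estimated correlation and 0.106 without untreated replicate 1. The G2/M list had 1 of 39 lower, ECT2 (-1.52 ± 0.28), and 0 higher, at 0.0273, with adjusted p = 0.736 with an estimated correlation. It lost its call without untreated replicates 1 and 3 (0.420 and 0.0846) or 72 h replicates 2 and 3 (0.113 and 0.132). Fibroblast markers had 1 of 8 higher, LUM (2.61 ± 0.27), and 1 lower, FBLN1 (-0.82 ± 0.29), at 0.979, with a median of -0.20 and a mean of 0.07. FBLN1 missed the threshold without untreated replicates 1 and 2 (0.146 and 0.0718) or 72 h replicates 2 and 3 (0.0927 and 0.101), and as the mean of its probe sets (-0.25, 0.406).

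**Figure D2:**
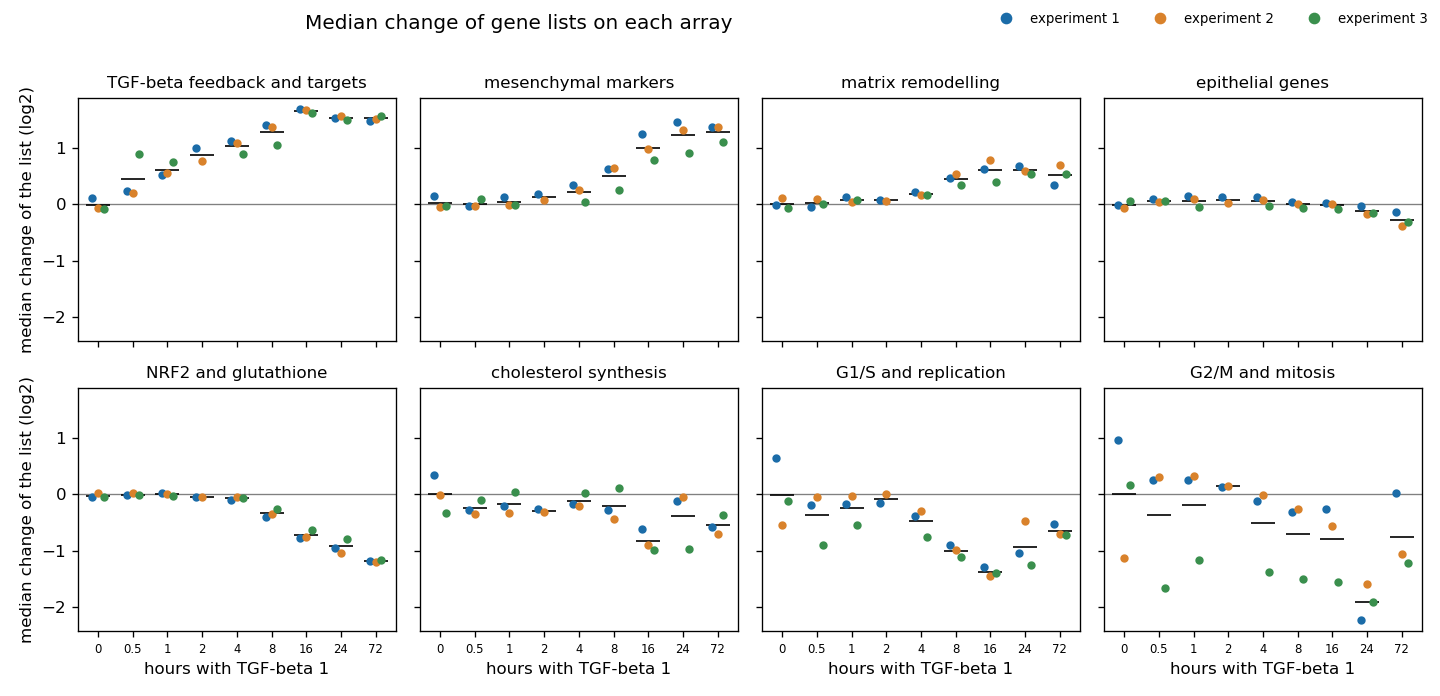
Median log2 change of 8 gene lists on each array from the mean of the untreated arrays (vertical axis) at each time with TGF-beta 1 (horizontal axis, hours), with points coloured by experiment and a bar for the mean over arrays. The medians of the G2/M list lay at 0.97, -1.13 and 0.17 on the untreated arrays and at -2.22, -1.58 and -1.90 on the 24 h arrays.

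The comparison of 24 h with 1 h asks which changes came late. IGFL1 was 160.1-fold higher at 24 h (7.32 ± 0.44, adjusted p 4.33e-11), with IGFBP7 (6.10 ± 0.52), IGFBP5 (6.06 ± 0.58), COL5A1 (5.83 ± 0.50) and CORO2B (5.34 ± 0.25). TM4SF20 (-5.75 ± 0.45), RARRES1, a retinoid-responsive gene (-4.87 ± 0.45, to a mean of 6.52 under the level of zero signal), SLC7A2 (-4.86 ± 0.32), TSPAN8 (-4.82 ± 0.38) and AGR2 (-4.65 ± 0.30) were lower. SMAD7 (0.01 ± 0.38, adjusted p 0.989) and SKIL (0.04 ± 0.30, adjusted p 0.934) did not differ by more than the replicate error. In all, 4560 genes differed, 1918 higher and 2642 lower, or 2802 genes without the 3 arrays marked with r, which leaves 1 array at 24 h. NRF2 genes had 26 of 27 lower and 0 higher (26 and 0 adjusted over the list alone), led by ALDH3A1 (-4.59 ± 0.26) and AKR1C2 (-3.05 ± 0.28), at 8.51e-18 (0.00118 with an estimated correlation). Mesenchymal markers had 14 of 24 higher and 0 lower (18 and 0 adjusted over the list alone), led by CDH2 (3.34 ± 0.27) and MMP2 (2.84 ± 0.29), at 2.44e-09 (0.0120 with an estimated correlation). Immediate-early regulators had 5 of 28 higher and 6 lower (5 and 7 adjusted over the list alone), led by FOS (-3.56 ± 0.38) and EGR2 (3.42 ± 0.41), at 0.975. Of 15 lists past the threshold, 5 kept the call with an estimated correlation. Epithelial genes (0.0404, adjusted p = 0.362 with an estimated correlation) lost theirs with the experiment as a block (0.0673) and without 24 h replicates 2 and 3 (0.0528 and 0.0654), and interferon-stimulated genes (0.0209, adjusted p = 0.410 with an estimated correlation) without 1 h replicate 2 (0.0560).

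The comparison of 72 h with 24 h asks whether expression still moved after the first day. IGFL2 was 14.2-fold higher at 72 h (3.82 ± 0.35, adjusted p 2.68e-07) and the NADPH oxidase NOX4 6.96-fold higher (2.80 ± 0.17, adjusted p 5.07e-10). The matrix proteoglycan gene LUM (2.56 ± 0.27), PLPP4 (2.41 ± 0.33) and the neuropeptide gene VIP (2.37 ± 0.34) were also higher. MUC5B (-5.17 ± 0.34), LCN2 (-3.77 ± 0.44), vitronectin gene VTN (-3.68 ± 0.58, to a mean of 5.81 under the level of zero signal), the cystatin CST1 (-3.54 ± 0.41) and SLPI (-3.25 ± 0.29) were lower. In all, 1347 genes differed, 690 higher and 657 lower. Epithelial genes had 7 of 35 lower and 1 higher (7 and 2 adjusted over the list alone), led by CLDN2 (-2.13 ± 0.53) and CDH1 (-0.92 ± 0.17), at 0.0252. Unfolded protein genes had 3 of 26 lower and 0 higher (3 and 0 adjusted over the list alone), led by DNAJC3 (-1.39 ± 0.16) and ATF6 (-0.70 ± 0.15), at 0.0252. The G2/M list was higher at 72 h (median 1.10, 2.47e-06), with 0 of 39 past the threshold by limma over all genes or adjusted over the list alone. With an estimated correlation each of these lists gave adjusted p = 0.707. The epithelial list lost its call without 24 h replicate 1 (0.0867) or 72 h replicate 2 (0.0749), and unfolded protein genes without 24 h replicate 1 (0.0610) or 72 h replicates 2 and 3 (0.0507 and 0.0854). CLDN2 missed the threshold without 24 h replicate 3 (0.0866) or 72 h replicates 1 and 2 (0.0533 and 0.0773), and ATF6 as the mean of its probe sets (-0.38, 0.103). The count was 679 without 24 h replicate 1, 881, 628 and 812 without 72 h replicates 1, 2 and 3, and 156 without the 3 arrays marked with r, where again 1 array is left at 24 h.

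Of the genes chosen in advance, SKIL passed from 0.5 h on, as the plot of levels shows. SMAD7 lay at 10.08, 11.51 and 12.43 on the 0.5 h arrays, against a highest untreated value of 9.82, and its call at 0.5 h was lost in the fits named above. SMAD7 rose by 2.53 ± 0.38 at 24 h and 2.63 ± 0.38 at 72 h, and SKIL by 2.15 ± 0.30 and 1.90 ± 0.30. CDH1, which encodes the junction protein E-cadherin, fell by 0.50 ± 0.17 at 8 h (adjusted p 0.0323), 2.17 ± 0.17 at 16 h, 3.34 ± 0.17 at 24 h and 4.26 ± 0.17 at 72 h. On the 8 h arrays CDH1 lay at 12.44, 12.67 and 12.68, against a lowest untreated value of 13.09. CDH2, which encodes N-cadherin, rose by 1.84 ± 0.27 at 8 h, 2.89 ± 0.27 at 16 h, 3.09 ± 0.27 at 24 h and 3.74 ± 0.27 at 72 h. SNAI2, a repressor of E-cadherin, rose by 1.54 ± 0.34 at 4 h and 4.43 ± 0.34 at 72 h. VIM, which encodes vimentin, had a level of 13.96 ± 0.41 (SD, n = 3) in untreated cells and rose by 0.63 ± 0.14 at 8 h and 0.88 ± 0.14 at 24 h and at 72 h, and as the mean of its probe sets it passed at 4 h as well (0.82). FN1, which encodes fibronectin, rose by 0.99 ± 0.26 at 16 h, 1.38 ± 0.26 at 24 h and 1.85 ± 0.26 at 72 h. SNAI1, another repressor of E-cadherin, passed only at 24 h (0.83 ± 0.27, adjusted p 0.0182) and stood at 0.06 ± 0.27 at 72 h. ZEB1, of the same kind, rose by 0.79 ± 0.28 at 24 h (adjusted p 0.0294) and 1.45 ± 0.28 at 72 h. Without single arrays, CDH1 at 8 h missed the threshold without untreated replicates 1, 2 and 3 (0.0730, 0.0668 and 0.0699) and 8 h replicates 1 and 2 (0.133 and 0.0554), and FN1 at 16 h without untreated replicate 1 (0.0544). SNAI1 at 24 h did so without untreated replicate 1 (0.103), 24 h replicates 1 and 2 (0.0874 and 0.0910) and with only these groups in the fit (0.0651), and ZEB1 at 24 h without untreated replicates 1 and 2 (0.130 and 0.0546) and 24 h replicates 2 and 3 (0.0812 and 0.0975).

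**Figure D3:**
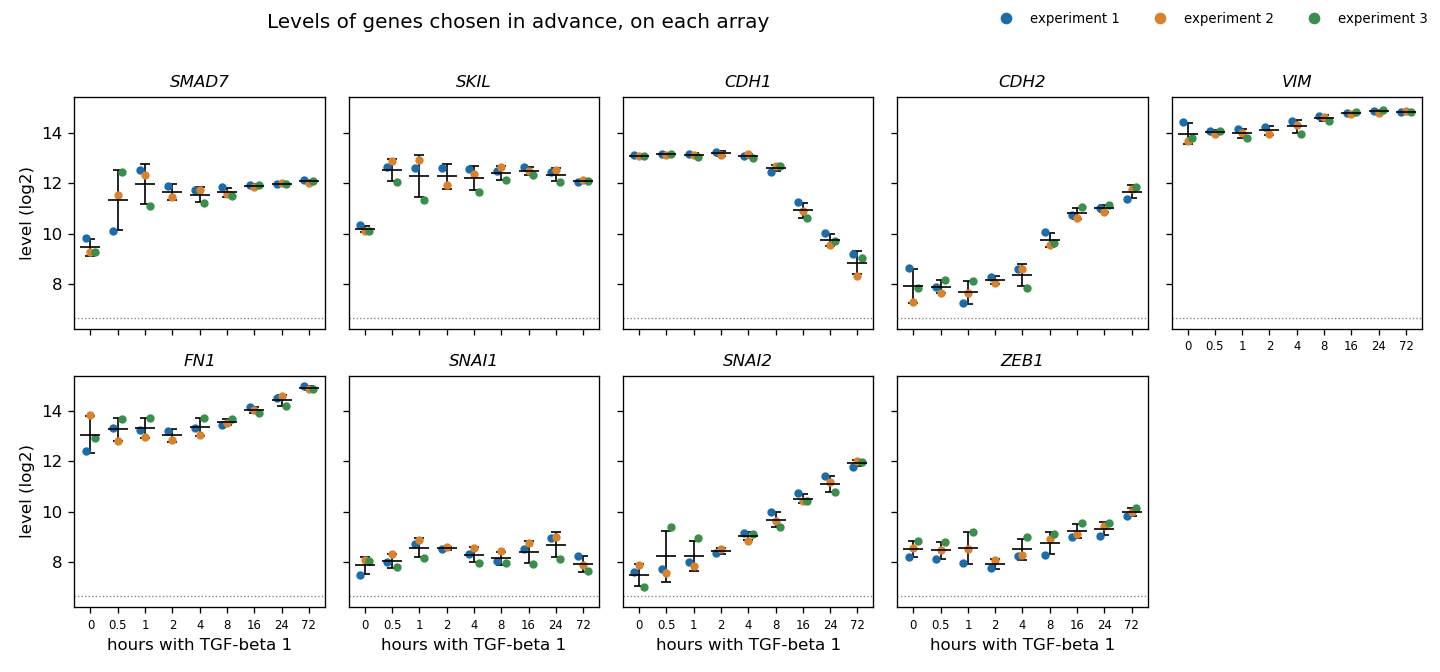
Level (vertical axis, log2 signal) of genes chosen in advance on each array at each time with TGF-beta 1 (horizontal axis, hours), with points coloured by experiment, bars for group means, whiskers for SD, and a dotted line at the level of zero signal, 6.64. CDH1 goes from 13.09 in untreated cells to 8.84 at 72 h, and CDH2 from 7.91 to 11.65.

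The authors' deposited selection, at p under 0.001 and more than 2-fold either way, held 63, 126, 361, 642, 1530, 2711, 2975 and 3238 probe sets at the successive times from 0.5 h on. At 24 h, 1589 of these were higher and 1386 lower, and at 72 h 1691 and 1547. These count probe sets under another rule, while the numbers above count genes.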

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

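The tests of the G2/M pattern, of the G1/S pattern and of the experiment numbers were chosen only after these patterns had been seen, the differences with exchanged numbers after the other values, and the margin of the G2/M test was set after its value was known.

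The G2/M and mitosis genes differed between times as a list, with a median log2 change of 1.10 from 24 h to 72 h by a test of the difference itself (camera adjusted p 2.47e-06, and adjusted p = 0.707 with an estimated correlation). No gene of the list passed alone. The list's median lay at -2.22, -1.58 and -1.90 on the 24 h arrays and at 0.03, -1.06 and -1.22 on the 72 h arrays, relative to the untreated mean. The untreated arrays lay farther apart from one another than this change, as the plot of list medians shows. A candidate technical explanation is the letter r that the authors' table gives 24 h replicates 1 and 3 and 8 h replicate 3, whose meaning the files do not state. The 24 h array without it stood at -1.58, beyond the bound of -1.3 but by less than the SD of 0.32 of the 24 h arrays, so this stays open, and without the 3 arrays the difference from 24 h to 72 h was 0.72 (adjusted p 0.00486), a test with 1 array left at 24 h that is assumed to vary like the other groups. A change with time under TGF-beta 1 and one with time in culture also stay open, since no untreated cells of the same age are among the arrays.

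The G1/S genes were lower as a list at 0.5 h, a short time for such a change. Leaving out 1 untreated array moved the adjusted p to as much as 0.583, without untreated replicate 1, where the median was -0.04, while it was 1.06e-17 and 1.63e-08 without replicates 2 and 3. The call also ended without a treated array, 0.5 h replicate 3 (camera adjusted p 0.107). The same-number difference of the list mean was -0.77 in experiment 1, 0.51 in experiment 2 and -0.71 in experiment 3, or -0.77, 0.10 and -0.29 with the numbers of untreated replicates 2 and 3 exchanged, so under neither numbering was the list lower in every experiment. These values are in line with a high level of these genes on untreated replicate 1 (median 0.65, against -0.55 and -0.12 on replicates 2 and 3) and with shifts between experiments, and the tests do not separate these explanations. An effect of TGF-beta 1 on the list within 0.5 h was not tested apart from them.

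After group means were removed, untreated replicates 2 and 3 did not deviate together with the other arrays of their own experiments, and untreated replicate 2 correlated at a mean r of 0.312 across genes with the arrays of experiment 3 and of -0.136 with those of experiment 2. Untreated replicate 3 showed little preference, at 0.0357 with experiment 2, -0.0128 with its own and -0.0160 with experiment 1, while 23 of 26 arrays correlated best with their own experiment. Exchanging the numbers of untreated replicates 2 and 3 lowered the median residual variance of the blocked fit to 0.943 times its value, the lowest of the 6 numberings, and in each of the 7 other groups of 3 arrays the numbers as given were lowest. Giving untreated replicates 1, 2 and 3 the numbers 2, 3 and 1 came close, at 0.958, so the variance hardly separates these numberings. Both give untreated replicate 2 the number 3. A candidate explanation is an exchange of the experiment numbers of untreated replicates 2 and 3. Such an exchange would not move the unblocked values of the report. From 0.5 to 24 h the authors' array numbers run in order of time within each experiment. Each of the untreated arrays 2 and 3 is numbered just ahead of the other experiment's run. The authors' p-values lay nearer to a refit of their model with the numbers as labelled than exchanged. The median difference in log10 p was 0.00613 against 0.0181 at 24 h. This bears on which numbers the authors used, not on whether the numbers are right. No array was assigned by its number, the labels were kept, and no biological explanation was tested.

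Outside the gene tests, 1337 of 6492 probe sets without a gene symbol changed at 24 h (20.6 percent, against 30.3 percent of probe sets with 1 gene).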

How the results depend on the processing

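The exchanged experiment numbers and the fit without the 3 arrays marked with r were chosen only after the results were seen. The gene values that follow cover 758 results, each a called gene in a comparison, picked by the rule for named genes. They do not stand for all called genes. Over all genes, for instance, 997 of the 1355 calls at 4 h were kept without untreated replicate 2. Of 8126 values of the picked genes under other settings, 7960 kept their direction and their side of the threshold. Another 164 kept their direction only and 2 reversed. The 8126 include 758 values from centring on the median and 758 from a second quantile normalization, which do not test stability. Of 4500 values with 1 array left out, 4075 kept both, 425 kept the direction only and 0 reversed. Genes picked because the arrays of the groups compared did not overlap cannot reverse without 1 array. The 0 was thus partly set by the rule for named genes. Among other settings, the fit on only the groups compared ended 63 of 581 picked gene calls. That fit has fewer arrays and degrees of freedom, and it also takes the spread from the compared groups alone. These reasons were not tested apart. The mean of a gene's probe sets ended 52 of 747 with the direction kept and the 2 that reversed. With the experiment as a block, 2 of the picked gene calls ended, and no count over all genes moved by more than 1.5 times. Centring on the median moved nothing, and a second quantile normalization moved values by at most 0.0562, so neither tests stability. The second deposited table gave no other value, so that alternative was not run. Signal over background limits the results: levels near 6.64 carry no signal, so a fall to that level understates the change, and a rise from it rests on an understated fold. Where no cause is named below, the cause was not tested.

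Counting all probe sets, 45, 173, 794, 2361, 6255, 9548, 9914 and 11533 passed at the 8 times in order, 8577 between 24 h and 1 h, 2472 between 72 h and 24 h and 14079 in the F test, as more features were tested. With only the groups compared in the fit, 2, 24, 291, 781 and 2225 genes passed from 0.5 to 8 h. An adjusted p under 0.01 left 13, 45, 186, 731 and 2079 from 0.5 to 8 h, and a change of at least 2-fold left 204, 410, 887, 1485, 1651 and 1690 from 2 to 72 h, as stricter rules do. The block with exchanged numbers gave 135 at 1 h, 723 at 2 h and 2278 between 72 h and 24 h. Without the arrays marked with r, 3223 passed at 24 h, 2802 between 24 h and 1 h and 156 between 72 h and 24 h, with fewer arrays, the lone 24 h array being assumed to vary like the other groups. With an estimated correlation 2 lists passed at 0.5 h, 2 at 2 h, 1 at 4 h, 3 at 8 h, 8 at 16 h, 9 at 24 h and 6 at 72 h, and with fry 2 passed at 0.5 h.

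Leaving out 1 array gave 13 to 42 genes at 0.5 h, 44 to 106 at 1 h, 68 to 383 at 2 h, 836 to 1427 at 4 h, 2621 to 3189 at 8 h, 4213 to 4554 at 16 h, 4261 to 4921 at 24 h and 4727 to 5193 at 72 h. It gave 3638 to 4584 between 24 h and 1 h and 628 to 1147 between 72 h and 24 h, and leaving out 1 experiment gave 3493 to 6640 in the F test. For lists the ranges were 3 to 8 at 0.5 h, 5 to 7 at 1 h, 4 to 8 at 2 h, 8 to 12 at 4 h, 14 to 17 at 8 h, 14 to 16 at 16 h, 16 to 17 at 24 h and 16 to 19 at 72 h. At 0.5 h, 3 lists passed without untreated replicate 1 and without 0.5 h replicate 3, and at 2 h, 8 without untreated replicate 2.

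As the mean of their probe sets, the called genes TEK at 24 h (0.0371) and ILK between 72 h and 24 h (0.13) reversed, since other probe sets of these genes go the other way. Genes that did not pass also changed sign. As the mean of probe sets CDH2 gave 0.0333 and ZEB1 -0.0484 at 1 h. With 1 array left out, the change at 1 h ranged from -0.0211 to 0.0503 for CDH1, from -0.56 to 0.11 for CDH2, from -0.14 to 0.25 for VIM, from -0.0660 to 0.66 for FN1 and from -0.29 to 0.33 for ZEB1. At 4 h it ranged from -0.0471 to 0.0209 for CDH1, from -0.0195 to 0.71 for FN1 and from -0.26 to 0.13 for ZEB1, and at 72 h from -0.13 to 0.21 for SNAI1.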

Other observations

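The families of gene symbols described next were tested only after the results were seen, over 462 families per comparison and without the other settings. The IFITM genes, which encode interferon-induced membrane proteins, fell together at 24 h, with 5 of 5 lower (median -1.86, camera adjusted p 0.00300), such as IFITM3 (-2.34 ± 0.18) and IFITM2 (-2.14 ± 0.16). At 72 h this family stood at a median of -1.85 with 5 of 5 lower (adjusted p 0.00162). Probe sets of these similar genes can bind one another's transcripts. The AKR family of aldo-keto reductases had 9 of 11 lower and 0 higher at 24 h (adjusted p 0.00300), a family that shares members with the NRF2 list. Genes of the large subunit of the mitochondrial ribosome (MRPL) had 23 of 50 lower and 0 higher at 24 h (median -0.26, adjusted p 0.0273) and 26 of 50 lower at 72 h (adjusted p 0.00199). Genes of intraflagellar transport (IFT) had 6 of 18 higher and 0 lower from 24 h to 72 h (median 0.34, adjusted p 0.00897). With an estimated correlation none of these passed, at adjusted p = 0.388 for IFITM and AKR, adjusted p = 0.918 for MRPL at 24 h, and adjusted p = 0.793 for IFT.

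Of 14771 genes, 1 passed in opposite directions at 1 h and 24 h and 9 at 24 h and 72 h with the difference past the threshold as well, and those given here were chosen after their values were seen. A test of the difference adds little for genes picked in this way. NANOS1, an RNA-binding repressor, rose by 1.33 ± 0.22 at 1 h and fell by 0.66 ± 0.22 at 24 h. ST3GAL5, a sialyltransferase, rose by 1.04 ± 0.20 at 24 h and fell by 0.65 ± 0.20 at 72 h, and LMNA, which encodes lamin A and C, rose by 0.38 ± 0.12 and fell by 0.66 ± 0.12. VLDLR, a lipoprotein receptor, fell by 0.50 ± 0.15 at 24 h and rose by 0.83 ± 0.15 at 72 h, and CTTNBP2 fell by 0.90 ± 0.28 and rose by 0.91 ± 0.28.

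Other splits of the arrays were counted as a planned test. For the F test, 1 of 100 splits of the 26 arrays, the real one, gave as many as 7040 genes, and the highest other gave 1871. This argues against groups that are interchangeable as a whole, but it does not speak for each of the 7040 genes. The other splits were drawn at random without regard to experiment. For 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. The real split was the only 1 of the 10 with as many genes at each time with 3 arrays and for both differences, and 2 h, with 2 arrays, was not split. It gave 20 genes at 0.5 h against 2 in the highest other split, 80 against 1 at 1 h, 1355 against 113 at 4 h, 3413 against 26 at 8 h, 4975 against 0 at 16 h, 5201 against 22 at 24 h and 5659 against 0 at 72 h. For 24 h with 1 h it gave 4560 against 5, and for 72 h with 24 h 1347 against 2. Every other split mixes arrays of the groups compared, so a real change between them adds to the spread and can lower the count of genes. Part of that change also stays between the mixed sets and can raise the number of lists. At 16 h, for instance, another split gave 0 genes but 15 lists. The counts of other splits are thus not those to be found without an effect. The numbers of lists stood out less, which for this reason says little about the lists either way. At 0.5 and 1 h, 3 of the 10 splits gave as many as the real 6, and the highest other gave 7. From 4 h on only the real split, 1 of the 10, reached its number, with 12 lists against 11 at 4 h, 16 against 13 at 8 h, 16 against 15 at 16 h, 17 against 13 at 24 h and 19 against 14 at 72 h. Among the 3 other splits that part the arrays of every experiment, the highest numbers of lists were 5, 6, 11, 13, 15, 12 and 13 at these 7 times.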
